A study of Mus musculus with 23 samples.

How the data were processed

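RNA was taken from mouse skin (day 0) and from wounds (days 3, 7 and 10), and sequenced as 50 base single reads from stranded total RNA libraries (SMARTer Stranded Total RNA Pico v2), per the labels. STAR (version not given) and genome build GRCm39 are named in the submitters' processing notes. The counting tool, annotation and strand setting are not given in the sources used here. The deposited table holds whole-number counts per gene for 23 libraries, which the authors left without normalization as far as the values show: totals differ between libraries, from 33080930 to 37494760. No nameless entries and no unmapped columns were present. Reads that match both a mitochondrial gene and its nuclear copy cannot be told apart: Gm28661 and mt-Co2 had a ratio of 1 in all 23 libraries, and nuclear copies held 2.34% to 9.84% of the counts. No coordinates are given, because the reference at hand is of another build (GRCm38) than that of the authors.

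Groups were taken from the labels (treatment and day). The design text speaks of fewer time points than the 4 days in the labels, and all 4 were used. Replicates of a group are separate mice by their label numbers, 17 in all, so that p-values measure the spread between labelled biological replicates. On days 0 and 3 a treatment shares its numbers, read here as the same animal sampled on both days, which makes the numbers pair the samples by design. Correlations of the deviations of same-numbered libraries from their group means were -0.08, -0.04 and -0.08 in control and 0.26, -0.11 and 0.26 in adalimumab. The number of changed genes with the animal as a block is therefore given for day 3 against day 0 and for its interaction. That block was fitted to the libraries of days 0 and 3 alone. Its counts thus differ from the main fit in the libraries used as well as in the pairing. Values of single genes and lists in those contrasts come from the fit without the block and ignore the pairing. No 2 libraries of a group held the same values.

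Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr by group with a minimum count of 10 and a minimum total of 15, glmQLFit and glmQLFTest, 1 mean per group over all 23 libraries). P-values were adjusted by Benjamini and Hochberg over the 23083 genes tested, with a threshold of 0.05. The common dispersion was 0.181 (a biological coefficient of variation of 42.5%), TMM factors ran from 0.861 to 1.184, and the median SE of a treatment difference was 0.415 to 0.471. Values after ± are SE of log2 differences or, for CPM, SD. A total of 497 members in lists of cell types and pathways were fixed, 494 were in the table and 490 tested. The 30 lists were tested with limma 3.58.1 camera (preset correlation 0.01, log CPM with a prior count of 3), with an estimated correlation and the rotation test fry as alternatives. Scores are the mean over list members of log2 CPM relative to the mean of all libraries. A fold against a group with all libraries at 0 is replaced in list medians by its bound at a floor of 3 counts over the group. Such floors cover counting error only, since the reads carry no molecular identifiers.

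Named genes were chosen by rule: among genes past the threshold with a mean log2 CPM of at least 1, an ordinary symbol and groups that do not overlap, the 8 largest in each direction for treatment (5 for time and interactions), up to 3 genes per list by adjusted p, and 16 fixed genes. Where fewer than 10 genes passed, the 5 smallest p in each direction are given as values. From those, genes near 0 counts in a group were left out of the text after their values were seen, and so was Acod1, which passed in the day 3 interaction but stood at 0.0165 CPM in adalimumab day 0. Also left out were genes in time contrasts whose call ended when a single library was omitted, except Tnf and Il6. Groups, tests, lists, the naming rule and the alternatives listed next were set before the data were examined. Alternatives tried were DESeq2 1.42.0, RLE size factors, no or a stricter filter (at least 10 counts in every library of a group), fits of the compared groups alone, the replicate number or animal as a block, and leaving out each library. Added after seeing the data were limma voom with sample quality weights, removal of mitochondrial genes and copies, and omission of adalimumab day 0 replicates 2 and 3 or of adalimumab day 3 replicates 1 and 2.

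The edgeR step was tested on simulated data with all 23083 genes, 50 changed at each of 4 fold sizes. At log2 changes of 1, 2, 3 and 4 it recovered 30%, 66%, 80% and 88% of them for day 0, and 20%, 72%, 80% and 92% for day 3. For day 7 it recovered 24%, 72%, 94% and 88%, and for day 10, 2%, 62%, 88% and 94%. False calls numbered 5 of 137, 6 of 138, 5 of 144 and 7 of 130. In a simulation of day 7 with 1 shifted list, camera called that list and 0 others. In the measured libraries the median correlation estimated within lists was 0.574, above the preset value. Splits of the day 7 libraries other than the real one called up to 15 lists. Such splits called up to 465, 574, 188 and 0 genes on days 0, 3, 7 and 10. The simulations therefore do not show how often genes or lists are called falsely in the measured libraries.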

Results

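Gene expression was measured by RNA sequencing in skin and skin wounds of diabetic mice (HTNF ki/ki, Lepr db/db), which lack a working leptin receptor and heal slowly. Each mouse received 4 full-thickness wounds made with a 6 mm punch, and tissue was taken with an 8 mm punch on day 0, 3, 7 or 10. Mice were given vehicle (here called control) or adalimumab, an antibody that binds and blocks human tumour necrosis factor, at 20 mg per kg. The 23 libraries fall into 8 groups of 3, except adalimumab day 10 with 2. Total counts ranged from 33080930 to 37494760 per library, and 25289 to 29894 genes had at least 1 count. Of 56379 genes in the table, 23083 were tested. All 12 libraries of days 0 and 3 held transcripts of Xist, which is made from the inactive X chromosome of females (20168 to 50247 counts). Libraries of days 7 and 10 held transcripts of the Y-linked gene Ddx3y (2988 to 4913 counts), except adalimumab day 7 replicate 3, with 30365 counts of Xist and 2 of Ddx3y. Differences between days 0 or 3 and days 7 or 10 are therefore confounded with the sex of the mice and with the numbering series of the libraries. Reads of Tnf itself were few, 17 to 223 counts per library, and how reads from the HTNF allele were assigned is not given in the sources used here.

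The first question was whether the arms differed in skin of day 0. Day 0 was set in the design as the starting skin, so a difference there is read as one between the mice assigned to each arm. Genes of the growing hair follicle were higher in adalimumab day 0, led by Padi3, an enzyme that modifies proteins of the inner root sheath (log2 difference 9.67 ± 1.67 SE, adjusted p = 0.0481), and its substrate trichohyalin, Tchh (9.24 ± 1.76, adjusted p = 0.0481). Of 24 measured hair follicle genes, 6 rose (21 adjusted over the list alone), with a median log2 difference of 9.15, also 9.15 with the 4 members at 0 in 1 group set to their bound. The rise was not shared by the 3 mice: Tchh stood at 7.7, 697 and 6440 CPM (counts scaled to library size) in adalimumab replicates 1, 2 and 3, against 3.11 to 5.21 in control. Hair follicle scores were 0.27, 6.06 and 7.99 in these libraries and -0.81 to -0.67 in control. Pigment cell genes moved with them: 7 of 8 melanocyte genes rose adjusted over the list alone, 0 over all genes, with a median of 5.45 and scores of -0.09, 5.67 and 5.86.

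Cell division genes were also higher. Of 22 proliferation genes, 1 rose over all genes and 22 adjusted over the list alone (median 1.48), the single gene being the mitotic kinase Aurkb (1.57 ± 0.32; 18.6 ± 9.52 against 6.26 ± 1.22 CPM, SD, n = 3). Only the hair-rich libraries carried this: proliferation scores were 0.60 and 0.53 in adalimumab replicates 2 and 3 but -1.09 in replicate 1, within the -1.46 to -1.07 of control. Mki67, expressed in cycling cells, differed by 1.69 ± 0.40 without passing (adjusted p = 0.0565). Other genes that rose were Ticrr (2.69 ± 0.46), needed to start DNA replication, the exonuclease Exo1 (2.74 ± 0.52), the Wnt5a receptor Ror2 (3.23 ± 0.60), the TGF-beta pseudoreceptor Bambi (2.57 ± 0.52), Lrrc15 (7.11 ± 1.36), Lrrc75b (6.32 ± 1.12), Nckap5l (2.46 ± 0.46) and Lpcat4 (2.47 ± 0.48, or 1.58 without adalimumab replicate 3). The Lrrc15 difference turned in sign with adalimumab replicates 2 and 3 omitted, which leaves 1 library in that group. Serpinb6b was the single gene that fell (-1.88 ± 0.37). Inflammatory genes were lower by median without single genes passing. NF-kB target genes had a median of -1.15 (0 of 31 fell, 3 adjusted over the list alone) and cytokines and chemokines one of -1.16. Macrophage genes had a median of -1.11, M1-type activation genes -0.95, M2-type activation genes -0.87, interferon response genes -0.56 and hypoxia and glycolysis genes -0.72. Cxcl2, a neutrophil attractant, differed by -4.08 ± 1.63 (adjusted p = 0.272), Il1b by -2.75 ± 1.25 (adjusted p = 0.35), Tnf by -1.02 ± 0.67 (adjusted p = 0.547), the TNF receptor Tnfrsf1b by -1.08 ± 0.43 (adjusted p = 0.27) and the macrophage receptor Mrc1 by -0.78 ± 0.41 (adjusted p = 0.429). The differences of these 5 genes rested on control replicate 2, with 14.3 CPM of Cxcl2 against 0.386 and 0.517 in the others. Without it they were -0.62 for Cxcl2, 0.74 for Il1b, 0.89 for Tnf, -0.38 for Tnfrsf1b and -0.09 for Mrc1, the medians of NF-kB targets and cytokines were 0.02 and 0.00, those of macrophage, M1-type and M2-type genes -0.11, -0.16 and -0.27, and the calls of NF-kB targets (adjusted p = 0.495), cytokines (0.747), macrophage (0.674), M1-type (0.517) and M2-type genes (0.396) ended. The interferon response and hypoxia calls did not rest on it: without it their medians were both -0.50 (adjusted p = 0.00331 and 0.000167). Hypoxia scores were -0.07, -0.72 and -0.74 in adalimumab replicates 1, 2 and 3 and -0.16 to 0.31 in control, so only the hair-rich libraries lay below control.

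In all, 61 genes were higher and 1 lower at an adjusted p under 0.05 (edgeR quasi-likelihood), and 3066 had an unadjusted p under 0.05 where chance gives 1154. The limma camera test called hair follicle (adjusted p = 4.63e-21), proliferation (3.9e-20), melanocyte (1.13e-05) and 11 other lists. None held with an estimated correlation, where the adjusted p was 0.374 for hair follicle and proliferation and 0.673 for melanocyte. The count became 0 without control replicate 1, 2 or 3 or without adalimumab replicate 2 or 3, and 1503 without adalimumab replicate 1 (1220 higher, 283 lower). It was also 0 with RLE size factors, a stricter filter or a fit of these groups alone. DESeq2 gave 702 genes (592 higher, 110 lower) and limma voom 7334 (3908 higher, 3426 lower), so the balance of directions depended on the method.

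**Figure D1:**
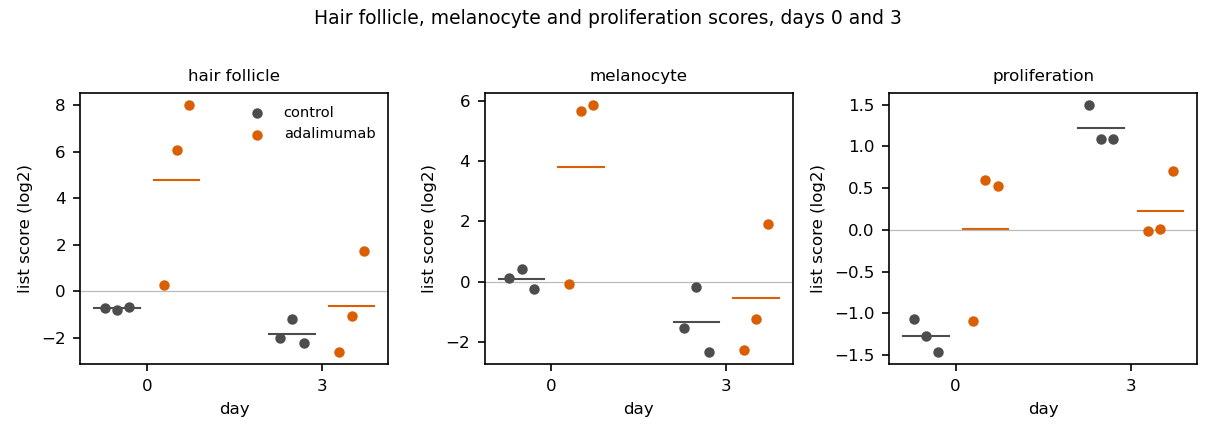
Hair follicle, melanocyte and proliferation scores (mean log2 CPM of the list members relative to all 23 libraries, vertical axes) of each library on days 0 and 3, in control (grey) and adalimumab (orange); horizontal lines are group means. Adalimumab day 0 replicates 2 and 3 have hair follicle scores of 6.06 and 7.99, above the 3.24 that is the highest of the other 21 libraries.

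On day 3 the question was whether blocking TNF changed early inflammation. Transcripts of inflammatory mediators were higher by value in adalimumab wounds but no single gene passed. The neutrophil attractant Cxcl2 had 451 ± 715 CPM against 13 ± 1.93 (SD, n = 3 each; log2 5.12 ± 1.56, adjusted p = 0.167), and the cytokines Il6 and Il1b differed by 3.72 ± 1.73 (adjusted p = 0.286) and 2.67 ± 1.20 (adjusted p = 0.274). Adalimumab replicate 2 dominated: its Cxcl2 level was 1280 CPM against 24.4 and 51.9, and its Il6 level 726 against 7.93 and 10.4. Without it the Il6 difference was -1.03 and that of Cxcl2 1.56. Among the genes with the smallest p were Pfkfb3 (2.14 ± 0.45), a driver of glycolysis, Irak2 (1.73 ± 0.34), a kinase of interleukin-1 signalling, Smad3 (1.1 ± 0.24), a transducer of TGF-beta, and Mical3 (1.45 ± 0.30) and Sipa1l1 (1.43 ± 0.31). Lower in adalimumab were Anln (-1.53 ± 0.29), a protein of the dividing cell's cleavage furrow, Dpysl3 (-1.55 ± 0.25), Rhobtb3 (-1.33 ± 0.24), Mex3b (-1.45 ± 0.29) and Gdf11 (-1.18 ± 0.24), each with adjusted p = 0.152.

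By list, camera called neutrophil genes up on day 3 (median 2.40, or 0.79 without adalimumab replicate 2; 0 of 19 rose, 9 adjusted over the list alone), with endothelium (1.91, or 3.55 without control replicate 2; 0 of 17, 14 alone), adipocyte (2.60, or 4.02 without control replicate 2 and 0.85 without adalimumab replicate 1; 0 of 16, 4 alone), erythrocyte (2.19, or 1.20 without adalimumab replicate 1; 0 of 8, 6 alone) and skeletal muscle genes (2.40; 0 of 16 by either adjustment). Proliferation genes were called down (-0.98; 0 of 22 fell, 20 alone), and so were fibrillar collagen and matrix genes (-0.57; 0 of 22 fell, 3 alone). No call held with an estimated correlation, the smallest adjusted p being 0.509. Medians of NF-kB targets (1.28), cytokines and chemokines (1.30), M1-type activation (1.30), hypoxia and glycolysis (0.88), growth factors (1.05) and heat shock genes (1.23) were called too, but ended without adalimumab replicate 2 (adjusted p = 0.486, 0.35, 0.0982, 0.116, 0.123 and 0.442), with medians of 0.10, 0.32, 0.28, 0.22, 0.42 and 0.33. The hypoxia and glycolysis median was 1.34 without control replicate 1. Without control replicate 2 the p of NF-kB targets was 0.0508 and that of cytokines and of M1-type genes 0.114, and without adalimumab replicate 3 that of cytokines was 0.0729. T cell (0.78), mast cell (0.56) and myofibroblast genes (0.92) were called and lost without adalimumab replicate 3 (0.0673), control replicate 3 (0.0638) and control replicate 3 (0.0879). Their medians moved with single libraries: T cell to 1.67 without control replicate 2, and mast cell and myofibroblast genes to 0.18 and 0.60, 3.38 and 1.90, and 0.00 and 0.59 without control replicate 1, 2 and 3, with mast cell genes at 0.93 without adalimumab replicate 3. Fixed genes that did not pass were Arg1 (1.87 ± 0.61, adjusted p = 0.181, and 0.47 without adalimumab replicate 2), an arginine-degrading enzyme of wound macrophages, the endothelial adhesion gene Pecam1 (1.99 ± 0.83, 0.241, but 3.76 with adjusted p = 0.0277 without control replicate 2), Mki67 (-1.01 ± 0.39, 0.216), Col1a1 (-0.73 ± 0.46, 0.427), Col3a1 (-0.91 ± 0.48, 0.343), Mrc1 (-0.72 ± 0.41, 0.376), Tnfrsf1b (0.39 ± 0.42, 0.674), the wound keratin Krt6a (1.58 ± 1.20, 0.519) and Tnf (0.96 ± 0.68, 0.492, and 0.45 without adalimumab replicate 2). Krt6a was at 2.95 without control replicate 2 and 1.03 without adalimumab replicate 3. Col1a1 was at -0.43 without control replicate 3 and -1.12 without adalimumab replicate 3, and Mrc1 at -0.43 without control replicate 1. Tnfrsf1b was at 0.17 and 0.64 without control replicates 2 and 3, and 0.19 without adalimumab replicate 1. Adalimumab replicate 1 stood apart in make-up: its epidermal differentiation score was -6.34 against -0.94 and 0.17 in the other replicates, its basal keratinocyte score -4.59 and its adipocyte score 3.54.

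EdgeR called 0 genes on day 3, with 3916 at an unadjusted p under 0.05, against 846 by DESeq2 and 0 by limma voom. The edgeR count was 837 without control replicate 2 and 328 without adalimumab replicate 3.

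**Figure D2:**
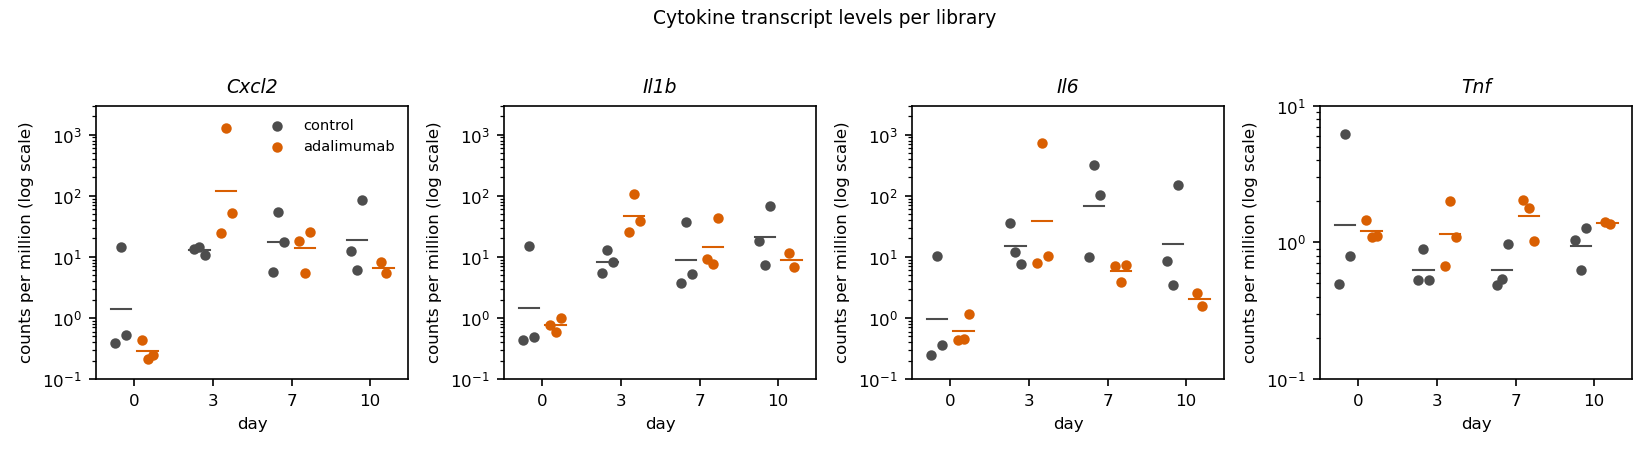
Levels of Cxcl2, Il1b, Il6 and Tnf (CPM, log axes; the Tnf axis covers a narrower range) in each library by day, in control (grey) and adalimumab (orange); horizontal lines are means of the log values. The highest Cxcl2 and Il6 points are both adalimumab day 3 replicate 2, at 1280 and 726 CPM.

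Day 7 asked whether the wounds differed during tissue formation. The list with the smallest camera p was that of the cornifying epidermis. All 21 measured epidermal differentiation genes were higher by value in adalimumab wounds, with a median log2 difference of 2.40, though 0 passed over all genes or adjusted over the list alone. Krt10, the keratin of differentiating layers, had 1030 ± 1210 CPM against 60.6 ± 13.1 (SD, n = 3 each; 4.09 ± 1.27). Its level was 54.8 in adalimumab replicate 1, 658 in replicate 2 and 2380 in replicate 3, without which the difference was 2.59. Camera called the list (adjusted p = 1.33e-12), not with an estimated correlation (adjusted p = 0.965), and the median lay between 2.12 and 2.92 when any single library was left out. Serpinb12 (4.00 ± 0.98), Mal2 (1.87 ± 0.47), the insulin-degrading enzyme Ide (2.02 ± 0.48), Tlcd3a (1.38 ± 0.37) and Krt6a (1.74 ± 1.20) were also higher by value. Lower by value were Il6 (-4.57 ± 1.81; 6.08 against 145 CPM), the nitric oxide synthase Nos2 (-2.64 ± 1.21), the glycogen regulator Ppp1r3c (-3.32 ± 0.99), the steroid carrier Star (-1.92 ± 0.58), Acot4 (-1.43 ± 0.31) and Acsl4 (-1.26 ± 0.38). Arg1 differed by 0.51 ± 0.59 and Tnf by 1.27 ± 0.69. Every one of these genes had adjusted p = 1. Single controls carried several of the lower values. Il6 stood at 9.91, 324 and 101 CPM and Nos2 at 5.16, 222 and 36.8 in control replicates 1, 2 and 3, and without replicate 2 the differences of Nos2 and Star were -0.57 and -0.47. Without control replicate 1 that of Ppp1r3c was -0.41.

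Weaker list calls on day 7 were neutrophil (median 0.30), T cell (0.50) and hair follicle genes (1.45, or 0.94 with members at 0 set to their bound) up, and skeletal muscle (-3.58, or -3.44 at the bound), hypoxia and glycolysis (-0.38) and growth factor genes (-0.35) down. Each had adjusted p = 0.965 with an estimated correlation, and each depended on single libraries. The muscle difference rested on control replicate 1, with a score of 3.03 against -5.73 and -4.86 in the other controls and -6.63, -4.89 and -0.63 in adalimumab. Without it the median was 3.36 and the call pointed up (adjusted p = 0.00248), while the call ended without adalimumab replicate 1 (0.603) and the median was -7.01 without replicate 3. The neutrophil call ended without control replicate 3 (median 0.01, adjusted p = 0.315) or adalimumab replicate 3 (0.05, 0.248), with medians of 0.62 to 0.86 without each of the others. The T cell call ended without control replicate 1 (median 0.24, adjusted p = 0.55) or adalimumab replicate 2 (0.18, 0.394) or 3 (0.54, 0.141), with medians of 0.94 and 0.85 without control replicate 2 and adalimumab replicate 1. The hair follicle call ended without control replicate 1 (0.0697) or 3 (0.0838) or adalimumab replicate 2 (median 0.47, 0.413) or 3 (0.141). The hypoxia call ended without control replicate 2 (median -0.12, 0.463) or adalimumab replicate 2 (-0.23, 0.0751) or 3 (-0.30, 0.164), and the growth factor call without control replicate 2 (-0.08, 0.312) or adalimumab replicate 1 (-0.11, 0.603). EdgeR called 0 genes, with 945 at an unadjusted p under 0.05, fewer than the 1154 chance gives, and DESeq2 called 6 and limma voom 2. Leaving out adalimumab replicate 1 gave 2 genes and 13 lists in place of 7.

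For day 10, with 2 adalimumab libraries against 3, epidermal differentiation genes had a median of 3.06 (0 of 21 rose, 11 adjusted over the list alone; camera adjusted p = 4.96e-09, adjusted p = 0.931 with an estimated correlation). Krt10 stood at 4320 ± 776 CPM (SD, n = 2) against 154 ± 49.4 (n = 3), a log2 difference of 4.81 ± 1.36 that did not pass (adjusted p = 0.199). Genes with the smallest p were Mal2 (2.81 ± 0.51), the peptidase Thop1 (2.04 ± 0.37), the Rac activator Tiam1 (1.86 ± 0.32), Serpinb8 (1.65 ± 0.27) and the transcription factor Zbtb7b (1.62 ± 0.30), each with adjusted p = 0.119. Zbed3 (-1.1 ± 0.24, 0.157), Hoxd8 (-0.82 ± 0.19, 0.186), Paip1 (-0.69 ± 0.16, 0.186) and Cfap36 (-1.02 ± 0.24, 0.186) were lower by value. Mitochondrially encoded genes were lower as a group (median -1.70; 0 of 15 fell, 15 adjusted over the list alone; camera 1.06e-11, and adjusted p = 0.931 with an estimated correlation). They took 4.44% and 4.41% of the counts in the adalimumab day 10 libraries, the lowest of all 23, against 12.1%, 7.1% and 18.1% in control day 10 and 18.1% as the highest. With mitochondrial genes removed the epidermal differentiation median of day 10 was 3.11. Of the fixed genes these did not pass: Il6 differed by -4.68 ± 2.19 (0.348), Cxcl2 by -2.34 ± 1.62 (0.534), Il1b by -1.74 ± 1.35 (0.582), Nos2 by -2.04 ± 1.38 (0.525), Tnf by 0.50 ± 0.74 (0.803), Krt6a by 2.39 ± 1.31 (0.42), Col1a1 by -0.41 ± 0.52 (0.761), Col3a1 by -0.28 ± 0.54 (0.86), Mki67 by -0.44 ± 0.44 (0.683) and Pecam1 by -0.55 ± 0.91 (0.831). Control replicate 3 carried the first 4 of these, with 149 CPM of Il6 against 8.72 and 3.43 in the other controls. Without it they were -1.53 for Il6, -0.45 for Cxcl2, -0.44 for Il1b and -0.26 for Nos2. Tnf was at 0.26 without control replicate 2. Mki67 was at -0.73 without adalimumab replicate 1 and -0.19 without adalimumab replicate 2, where the arm has 1 library.

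Camera also called hair follicle genes on day 10 (median 4.11, or 3.68 at the bound; lost without adalimumab replicate 1, with a median of 1.82 and adjusted p = 0.104) and endothelium genes (-0.82; lost without control replicate 2, 0.0532). Basal keratinocyte (1.66), wound-edge keratinocyte (1.47), hypoxia and glycolysis (0.42) and proliferation genes (-0.32) were called, and control replicate 2 ended the first (0.14), the second (0.138) and the last (0.182) of these. Control replicate 1 ended basal (0.0776), wound-edge (0.169) and hypoxia calls (0.18), adalimumab replicate 2 ended all 4 (0.08, 0.117, 0.294 and 0.134), and adalimumab replicate 1 ended the basal call (0.0518). The hypoxia median was 0.26 without control replicate 1 and 0.25 without adalimumab replicate 2. Each of these lists had adjusted p = 0.931 with an estimated correlation. The lists called numbered 8, but 4 without control replicate 2 and 5 without adalimumab replicate 2, where the arm has 1 library assumed to vary like the other groups. EdgeR called 0 genes, with 3245 at an unadjusted p under 0.05, against 413 by DESeq2, 5020 by limma voom and 1831 in a fit of these groups alone.

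**Figure D3:**
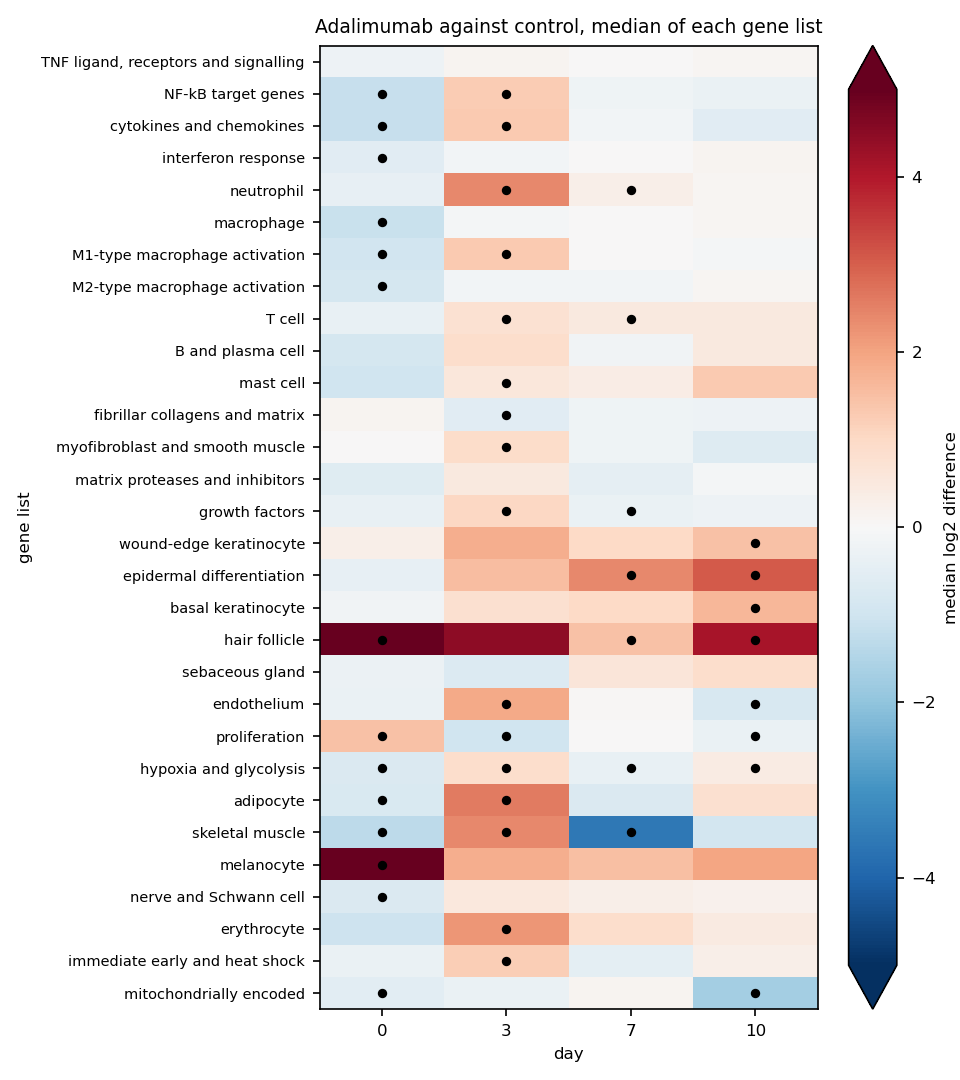
Median log2 difference, adalimumab against control, of each of 30 gene lists (vertical axis) by day (horizontal axis); dots mark camera calls at an adjusted p under 0.05, none of which held with an estimated correlation, and colours saturate at the ends of the bar. The medians furthest from 0 were hair follicle on days 0 (9.15), 3 (4.49, or 3.08 at the bound, not called) and 10 (4.11, or 3.68 at the bound), melanocyte on day 0 (5.45) and skeletal muscle on day 7 (-3.58, but 3.36 without control replicate 1). Epidermal differentiation genes were at 2.40 on day 7 and 3.06 on day 10.

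**Figure D4:**
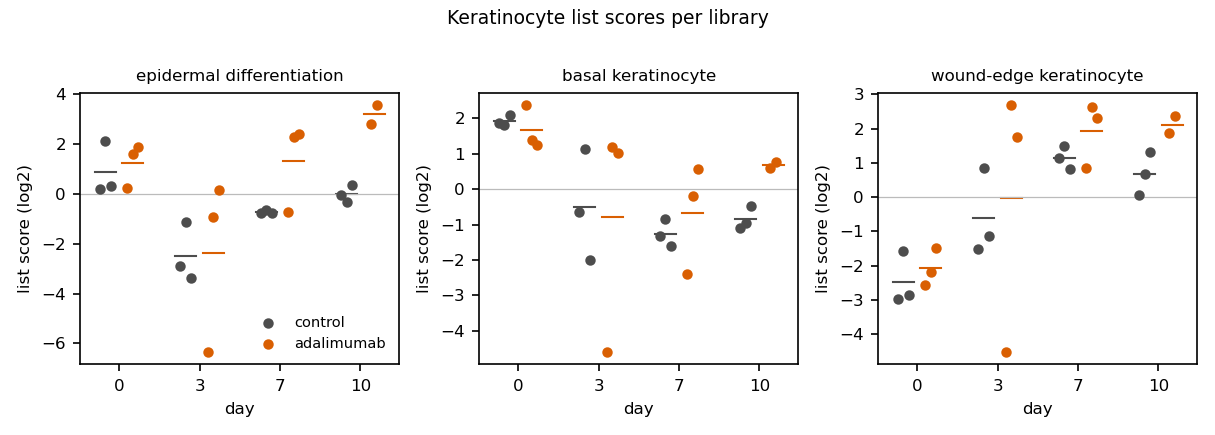
Scores of 3 keratinocyte lists (mean log2 CPM relative to all 23 libraries, vertical axes) in each library by day, in control (grey) and adalimumab (orange); horizontal lines are group means. On day 10 the epidermal differentiation scores were 2.83 and 3.56 in adalimumab and -0.34 to 0.37 in control, and adalimumab day 3 replicate 1 was at -6.34.

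The time course in control wounds was compared next, to show what wounding changed without the antibody. By day 3 all 16 macrophage genes had risen (median log2 change 3.02), among them the Fc receptor Fcgr1 (5.09 ± 0.54, adjusted p = 9.27e-06), the haemoglobin scavenger receptor Cd163 (4.43 ± 0.69, 0.000169) and Aif1 (4.59 ± 0.47, 7.57e-06), with Mrc1 at 1390 ± 656 against 77.2 ± 54.2 CPM. Interferon response genes rose in 23 of 28 cases, also 23 adjusted over the list alone (median 3.11; Oasl1 4.48 ± 0.57, Isg15 3.96 ± 0.51, Oas1a 4.03 ± 0.52). All 22 proliferation genes rose by either adjustment (median 2.42), such as Cdk1, the kinase that starts mitosis (2.81 ± 0.32), the survivin gene Birc5 (2.99 ± 0.35) and Mki67 (1.93 ± 0.40). Matrix genes rose in 18 of 22 (median 1.74), including Col1a1 (2.92 ± 0.49), Col3a1 (3.10 ± 0.52), the collagen cross-linker Loxl2 (4.05 ± 0.44) and the collagen hydroxylase P4ha3 (5.79 ± 0.60). The protease inhibitor Timp1 (6.31 ± 0.81), the neutrophil attractant Cxcl5 (11.45 ± 1.42), the formyl peptide receptor Fpr2 (6.23 ± 0.58) and Cthrc1 (6.36 ± 0.61) rose further. Mlkl and Ripk3, which act in necroptosis downstream of TNF receptors, rose by 3.03 ± 0.24 and 2.62 ± 0.30, as did Tnfrsf1b (1.73 ± 0.44, 0.00575). Tnf itself was at -1.93 ± 0.69 (0.0384), a call that ended without control day 3 replicate 1 (0.122) or 3 (0.116), and the value was 0.05 without control day 0 replicate 2.

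Genes of normal skin layers fell over the same 3 days. Adipocyte genes fell in 12 of 16 (15 adjusted over the list alone; median -3.84), such as adipsin, Cfd (-5.15 ± 1.17, 0.0029), and the lipase Lipe (-4.03 ± 0.89, 0.00243). Skeletal muscle genes fell in 14 of 16 (16 alone; median -5.06), along with Mstn (-8.31 ± 1.87, 0.00281), the muscle growth inhibitor myostatin, and Mylk4 (-9.02 ± 2.10, 0.00354). Epidermal differentiation genes fell in 11 of 21 (12 alone; median -2.83, or -4.31 without control day 3 replicate 2), with Krt10 (-4.83 ± 1.32, 0.00933) and Flg2 (-6.38 ± 1.54, 0.00446). Camera adjusted p was 3.25e-10 for macrophage and for matrix, 1.13e-15 for proliferation, 1.52e-11 for interferon, 1.69e-05 for adipocyte, 5.42e-05 for muscle and 0.000387 for differentiation genes. With an estimated correlation these had adjusted p = 0.433 (macrophage, matrix and proliferation), 0.476, 0.551, 0.615 and 0.624. In total 7986 genes changed, 4049 up and 3937 down, against 5115 without control day 3 replicate 1. With the animal as a block, in a fit of days 0 and 3 alone, the count was 5148 (2463 up, 2685 down).

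By day 7 the control wounds were rich in matrix transcripts. Matrix genes rose in 21 of 22 cases (median 3.41), and Col1a1 reached 14100 ± 3370 CPM from 431 ± 268 (5.03 ± 0.54, 6.54e-06) and Col3a1 33100 ± 9440 from 1070 ± 805. The fibroblast genes Cthrc1 (8.23 ± 0.67, 7.41e-07), Lrrc15 (8.79 ± 1.45, 0.00033) and Adam12 (4.31 ± 0.47) and the matrix genes P4ha3 (7.36 ± 0.63), Mmp14 (3.24 ± 0.28) and Timp1 (7.16 ± 0.84) rose. Matrix proteases and inhibitors rose in 15 of 21 (17 adjusted over the list alone; median 3.24, or 3.19 at the bound). Also above day 0 were Cxcl5 (12.32 ± 1.46), the calprotectin subunit S100a9 (6.98 ± 1.05), the acute phase gene Saa3 (7.23 ± 1.36) and Mrc1 (3.13 ± 0.44), and the division gene Cdk1 rose by 1.93 ± 0.31. Wound-edge keratinocyte genes rose in 11 of 19 and fell in 1 (13 rose adjusted over the list alone; median 4.09). Basal keratinocyte genes fell in 7 of 11 (median -2.33; Krt15 -8.94 ± 1.88, the epidermal regulator Trp63 -4.16 ± 1.02), and sebaceous gland genes in 10 of 15 (12 alone; median -4.11; Awat2 -5.71 ± 0.96, Scd3 -5.68 ± 1.17). Krt77 of the upper epidermis fell by 8.35 on the log2 scale, and 14 of 16 adipocyte genes fell (16 alone; Cfd -7.67 ± 1.33, Lipe -4.52 ± 0.91). Camera adjusted p was 4.47e-20 for matrix, 6.98e-08 for proteases, 1.26e-07 for adipocyte, 0.000101 for sebaceous gland, 0.000307 for wound-edge and 0.002 for basal genes. The first 3 had adjusted p = 0.119, 0.212 and 0.498 with an estimated correlation, wound-edge 0.526, and neither of the others held.

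Day 10 against day 0 in control gave a like set of matrix values: 21 of 22 matrix genes rose (median 3.45), with Col1a1 at 17800 ± 620 CPM (5.37 ± 0.55, 4.51e-06), Col3a1 at 4.88 ± 0.56, Cthrc1 at 8.02 ± 0.66, Lrrc15 at 9.03 ± 1.47, Adam12 at 4.78 ± 0.48 and Mmp14 at 3.57 ± 0.29. The endothelial genes Apln and Esm1 rose by 3.86 ± 0.41 and 3.60 ± 0.68, as did the chemokines Ccl3 (4.68 ± 0.75) and Cxcl5 (11.01 ± 1.40). Adipocyte genes fell in 15 of 16 (16 adjusted over the list alone; median -5.09), and the amino acid transporter Slc7a10 fell (-7.88 ± 1.80, 0.0032). Matrix had a camera adjusted p of 2.2e-20 (adjusted p = 0.113 with an estimated correlation) and adipocyte one of 8.75e-07 (0.58). On day 7, 7699 genes differed from day 0 (3778 up, 3921 down), and on day 10 the number was 7951 (3749 up, 4202 down). Both contrasts compare male with female mice.

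Between days 7 and 10 in control, edgeR called 0 genes, with 1185 at an unadjusted p under 0.05, against 24 by DESeq2 and 108 by limma voom. The growth factor Mdk (1.70 ± 0.42, adjusted p = 0.754), Cacnb4 (1.48 ± 0.37, 0.754) and Phactr1 (1.22 ± 0.30, 0.754) were higher by value on day 10, and Lgi2 (-1.88 ± 0.42, 0.637), the adhesion molecule Chl1 (-1.79 ± 0.40, 0.637) and Acot4 (-1.58 ± 0.31, 0.52) lower. Hypoxia and glycolysis genes had a median of -1.01 (0 of 17 fell, 4 adjusted over the list alone; camera 2.94e-12, adjusted p = 0.828 with an estimated correlation). Interferon response genes were called down (-0.73, or -0.42 without control day 7 replicate 3; camera 4.16e-08, adjusted p = 0.92 with an estimated correlation) and endothelium genes up (1.16; 5.72e-07, likewise 0.92). Skeletal muscle genes had a median of -1.38 and a mean of -1.45 while the camera test pointed up, and the median was 5.44 without control day 7 replicate 1.

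**Figure D5:**
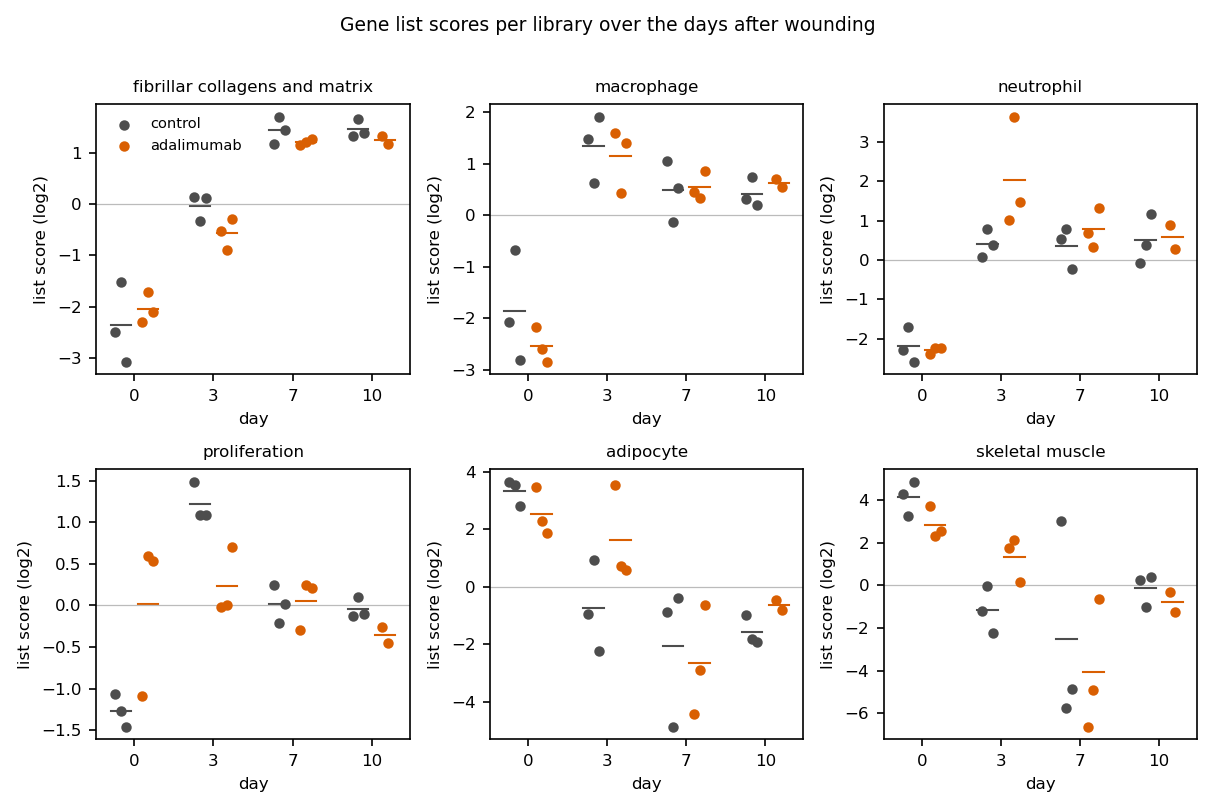
Scores of 6 gene lists (mean log2 CPM relative to all 23 libraries, vertical axes) in each library by day, in control (grey) and adalimumab (orange); horizontal lines are group means. Proliferation scores on day 3 were 1.09 to 1.49 in control and -0.02 to 0.70 in adalimumab.

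In adalimumab wounds the same contrasts were made. By day 3 Cxcl2 rose by 10.55 ± 2.02 (0.00147, and by 6.99 without adalimumab day 3 replicate 2), Il1b by 6.17 ± 1.43 (0.00569) and Il6 by 8.51 ± 2.19 (0.0109), the last at 3.76 (0.115) without adalimumab day 3 replicate 2. All 16 macrophage genes rose (median 3.70; Fcgr1 6.30 ± 0.57, the endotoxin co-receptor Cd14 6.19 ± 0.79), with Mrc1 (4.24 ± 0.46) and Arg1 (4.69 ± 0.69). Neutrophil genes rose in 15 of 19 (16 adjusted over the list alone; median 6.30, or 5.94 at the bound; Fpr2 7.54 ± 0.61), interferon response genes in 25 of 28 (27 alone; median 3.39; Oas3 5.76 ± 0.70) and cytokines in 21 of 35 (23 alone; median 3.81). Collagenase Mmp13 (7.70 ± 1.06), Timp1 (7.43 ± 0.85), Mlkl (3.07 ± 0.24) and Tnfrsf1b (3.21 ± 0.46) rose as well, and the TNF signalling list rose in 8 of 16 (median 0.67). Matrix genes rose in 10 of 22 (13 alone; median 1.00), and 0 of 22 proliferation genes changed (Mki67 -0.77 ± 0.39, 0.164, but -1.19 with adjusted p = 0.0105 without adalimumab day 0 replicate 1). Hair follicle genes fell in 22 of 24 (24 alone; median -7.08; Tchh -7.75 ± 1.65, or -4.99 without adalimumab day 0 replicate 3), and the chaperone Hspa1b fell (-4.63 ± 1.08). With adalimumab day 0 replicates 2 and 3 omitted, which leaves 1 library on that day whose spread is taken from the other groups, Tchh was at 0.55 and Mki67 at 0.83. Camera adjusted p was 3.92e-16 for macrophage, 7.82e-14 for neutrophil, 3.17e-20 for interferon, 1.76e-12 for cytokine, 0.000204 for TNF signalling, 8.99e-08 for matrix and 9.32e-10 for hair follicle genes. These had adjusted p = 0.0919, 0.0915, 0.13, 0.0919, 0.153, 0.224 and 0.322 with an estimated correlation. In total 4956 genes changed (2755 up, 2201 down), against 3142 without adalimumab day 0 replicate 2 and 2919 without replicate 3. With the animal as a block, in a fit of days 0 and 3 alone, the count was 1518 (1041 up, 477 down). An unpaired fit of the compared groups alone gave 1541. With only 1 library left in a group, and its spread taken from the other groups, the counts were 825 without both hair-rich libraries and 1616 without adalimumab day 3 replicates 1 and 2.

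On days 7 and 10 adalimumab wounds, too, were rich in matrix transcripts. Of 22 matrix genes, 21 rose on day 7 (median 3.12; Col1a1 4.10 ± 0.52, Col3a1 4.43 ± 0.55, Col5a2 3.21 ± 0.28, P4ha3 7.37 ± 0.64) and 21 on day 10 (median 3.43; Col1a1 3.95 ± 0.54, Col3a1 4.32 ± 0.57, P4ha3 7.11 ± 0.64). Cthrc1 rose by 7.68 ± 0.65 on day 7 and 7.05 ± 0.65 on day 10. Macrophage genes rose in 14 of 16 on day 7 (15 adjusted over the list alone; median 3.23) and 15 of 16 on day 10 (median 3.26). Proteases and inhibitors rose in 18 of 21 and fell in 1 on day 7 (median 3.32, or 3.16 at the bound; Timp1 7.10 ± 0.84) and rose in 16 on day 10 (17 alone; median 3.27; Mmp13 9.19 ± 1.13). Other genes that rose were Cstdc5 (10.48 ± 1.81), Mmp9 (3.86 ± 0.61) and Arg1 (3.49 ± 0.65) on day 7, and S100a9 (9.12 ± 1.16), Clec4d (6.18 ± 0.77) and the cytokine Tslp (5.00 ± 0.77) on day 10. Adipocyte genes fell in 15 of 16 on day 7 (median -4.56; Cfd -7.97 ± 1.36, resistin Retn -7.02 ± 1.51) and in 3 of 16 on day 10 (6 alone). Day 10 has 2 libraries, and their adipocyte scores were still low, at -0.8 and -0.48 against 1.87 to 3.45 on day 0. Skeletal muscle genes fell in 12 of 16 on day 7 (16 alone; median -5.30, or -5.19 at the bound and -8.49 without adalimumab day 7 replicate 3) and hair follicle genes in 22 of 24 (23 alone; median -7.96; Krt27 -10.25 ± 2.13, and -0.69 with the hair-rich libraries omitted, where day 0 has 1 library). The sebaceous gene Awat2 fell by 4.02 on the log2 scale. The day 10 calls of matrix (camera adjusted p = 8.1e-26) and proteases (4.3e-14) were the only 2 of all comparisons that held with an estimated correlation (adjusted p = 0.0309 for each). On day 7 the adjusted p with it was 0.113 for matrix and proteases, 0.239 for macrophage and 0.391 for adipocyte and hair follicle genes, and on day 10 it was 0.131 for macrophage genes.

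Day 7 gave 7500 changed genes (3377 up, 4123 down; 3923 of 7213 up with mitochondrial genes removed), 4730 without adalimumab day 7 replicate 1, 4612 in a fit of these groups alone and 2931 without both hair-rich libraries, where day 0 has 1 library. Day 10 gave 3331 (2082 up, 1249 down; 2368 of 3125 up with mitochondrial genes removed), 2179 without adalimumab day 0 replicate 2, 1932 without replicate 3. With 1 library left in a group, assumed to vary like the other groups, it was 1004 and 1055 without adalimumab day 10 replicate 1 and 2, and 737 without both hair-rich libraries. The median of all genes was -0.104 on day 7 and -0.159 on day 10, and -0.028 and -0.07 with RLE size factors. These contrasts share the confounding with sex. Between days 7 and 10 in adalimumab wounds edgeR called 0 genes, with 1618 at an unadjusted p under 0.05 (DESeq2 5, limma voom 2256, and 1 without adalimumab day 7 replicate 3). The lipoxygenase Alox12 (1.93 ± 0.56), the cold-shock protein Cirbp (0.93 ± 0.21) and Ptpn21 (0.68 ± 0.17) were higher by value on day 10, and Krtcap2 (-1.18 ± 0.25) and Haus3 (-0.94 ± 0.23) lower, each with adjusted p = 0.695. Mitochondrially encoded genes had a median of -1.53 (0 of 15 fell, 15 adjusted over the list alone; camera 1.29e-11, adjusted p = 0.819 with an estimated correlation).

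Whether the change since day 0 differed between the arms was tested as an interaction. The day 3 values that follow come from the fit without the animal as a block, and with that block every gene call of the day 3 interaction ended. The calls also ended in an unpaired fit of days 0 and 3 alone. On day 3, proliferation was the list with the most members past the threshold: 20 of 22 were more negative under adalimumab (22 adjusted over the list alone; median -2.51), such as Bub1 of the spindle checkpoint (-3.05 ± 0.57), cyclin Ccna2 (-2.94 ± 0.54), the transcription factor Foxm1 (-2.67 ± 0.47) and Mki67 (-2.70 ± 0.55), each with adjusted p = 0.0261. By median other lists differed more, such as skeletal muscle (3.68, with 0 passing) and hair follicle genes (-5.77, with 1 passing; -3.31 without adalimumab day 0 replicate 3 and -8.84 without adalimumab day 3 replicate 3). The day 0 values enter here: proliferation scores were -1.09, 0.60 and 0.53 in adalimumab day 0 and -1.46 to -1.07 in control. Also more negative were Padi3 (-9.03 ± 1.93, 0.0276), Lrrc15 (-8.00 ± 1.66, 0.0261) and the neuronal tubulin Tubb3 (-4.94 ± 1.08, 0.0299). The day 0 difference of Lrrc15 turned in sign with both hair-rich libraries omitted. More positive were Cxcl2 (9.20 ± 2.24, 0.0432), the phosphodiesterase Pde4b (4.32 ± 1.05, 0.0428), Ccrl2 (3.69 ± 0.78, 0.0268), the chemokine Ccl5 (3.01 ± 0.67, 0.0306) and the transglutaminase Tgm2 (3.99 ± 0.92, 0.0351). Cxcl2 was at 5.73 (0.164) without control day 0 replicate 2 and 5.64 (0.121) without adalimumab day 3 replicate 2, and without the latter Pde4b was at 2.58 (0.117). In the hypoxia and glycolysis list 2 of 17 passed (11 alone; median 1.76, or 0.94 without adalimumab day 3 replicate 2), Bnip3 (3.14 ± 0.71) and Tpi1 (1.78 ± 0.41), and NF-kB targets had 1 of 31 (15 alone; median 2.36, or 1.27 without control day 0 replicate 2 and 1.43 without adalimumab day 3 replicate 2). Camera adjusted p was 4.49e-22 for proliferation, 7.13e-07 for hypoxia and 3.48e-06 for NF-kB targets, and no list held with an estimated correlation (adjusted p = 0.458 at the smallest).

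At an unadjusted p under 0.05 (edgeR) the day 3 interaction had 2279 genes more positive and 2444 more negative, a closer balance than at the adjusted threshold. At that threshold it called 417 genes, 54 more positive and 363 more negative. It called 0 in a fit of days 0 and 3 alone, with or without the animal as a block. The fit of all libraries called 0 without control day 0 replicate 1, 2 or 3 or control day 3 replicate 1. It also called 0 without adalimumab day 0 replicate 2 or 3, or adalimumab day 3 replicate 1 or 2. It called 1778 without adalimumab day 0 replicate 1, 1316 and 244 without control day 3 replicates 2 and 3, and 1073 without adalimumab day 3 replicate 3. With RLE size factors the median of all genes in this interaction moved from 0.021 to 0.109. On days 7 and 10 edgeR called 0 genes, with 1724 and 3093 at an unadjusted p under 0.05, against 52 and 392 by DESeq2 and 1884 and 5134 by limma voom. Without adalimumab day 0 replicate 1 the edgeR counts were 348 and 560. Day 7 values included Serpinb12 (5.12 ± 1.31), the chemokine Ccl22 (2.96 ± 0.76), Draxin (-5.55 ± 1.18), Entpd3 (-4.34 ± 0.95) and Bambi (-3.34 ± 0.71), each with adjusted p = 0.52, and Krt10 (4.68 ± 1.66, 0.543). Day 10 values included Tiam1 (2.03 ± 0.43), Dusp22 (1.77 ± 0.38) and Tex264 (1.29 ± 0.28), each with adjusted p = 0.168, and Krt10 (5.40 ± 1.74, 0.203). Proliferation genes had medians of -1.40 and -1.87 (0 of 22 passed on either day, 21 and 19 adjusted over the list alone; camera 1e-14 and 3.88e-15, and adjusted p = 0.716 and 0.668 with an estimated correlation). These came mostly from day 0: mean proliferation scores were 0.02 in control and 0.06 in adalimumab on day 7, and -0.04 and -0.36 on day 10, but -1.26 and 0.02 on day 0, where the hair-rich libraries were at 0.60 and 0.53.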

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

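Tests on the hair follicle and epidermal patterns and all counts over other splits of the libraries were chosen only after the results were seen; those that compare day 0 with day 3 for the interaction genes were not.

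What draws a closer look is that the change from day 0 to day 3 differed between the arms by a tested interaction, for 417 genes in the unpaired fit. With the animal as a block, in a fit of days 0 and 3 alone, it called 0. An unpaired fit of the same libraries also called 0, so the loss cannot be credited to the pairing. The fit of all libraries called 0 without control day 0 replicate 1, 2 or 3 or control day 3 replicate 1. The same held without adalimumab day 0 replicate 2 or 3, or adalimumab day 3 replicate 1 or 2. The values below thus hold for the unpaired fit of all libraries. Among more positive genes the log2 differences of differences were 9.20 for Cxcl2, 4.32 for Pde4b, 3.99 for Tgm2, 3.69 for Ccrl2, 3.14 for Bnip3, 3.01 for Ccl5 and 1.78 for Tpi1. Of these Cxcl2 was at 5.73 without control day 0 replicate 2 and 5.64 without adalimumab day 3 replicate 2, and Pde4b at 2.58 without the latter. Among more negative genes they were -2.67 for Foxm1, -2.70 for Mki67, -2.94 for Ccna2, -3.05 for Bub1, -4.94 for Tubb3, -8.00 for Lrrc15 and -9.03 for Padi3. A possible explanation is that the arms already differed in the day 0 skin. Of the 54 more positive genes, 16.7% (9) had a larger difference between the arms at day 0 than at day 3, where the share over all genes was 46.3%. Their median difference was 1.74 at day 3 and -1.08 at day 0. By the limit set beforehand this goes against a day 0 difference as the whole cause. The genes were picked by the same contrast, though, with opposite signs at days 0 and 3 in 54 of 54, so the share does not decide. For the 363 more negative genes a day 0 difference cannot be told apart from an effect of the antibody. Among them 72.5% (263) had the larger difference at day 0 (median 1.14), but the median at day 3 was -0.84. With 10 ways to split the mice between the arms, the real one included and too few for a share under 0.05, the real count was 417 and the highest other 230, so that 1 of the 10, the real one, reached it. An effect of adalimumab remains open.

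Hair follicle genes were high in adalimumab day 0 replicates 2 and 3. RNA carried over from any of the other 21 libraries is argued against, because the highest hair follicle score among them was 3.24 against 6.06 and 7.99. Carry-over from replicate 3 into replicate 2, or from outside the series, was not tested. A difference in library size is argued against by a ratio of 0.98 of their mean total counts to those of the other 4 libraries of day 0. Mice whose follicles were in the growth phase on day 0 may account for it: the lower melanocyte score of the pair was 5.67, against 2.11 as the highest elsewhere, and on day 3 the same mice had hair follicle scores of -1.06 and 1.73, above the -1.20 of the next library, the first of them by less than the margin of 1 set for this test. The melanocyte score of that mouse on day 3 was -1.25, below the -0.19 of control replicate 2. This was not decided, because growth phase was not recorded and the site of the punch and depilation stay open. Day 0 was set as the starting skin, where an effect of the antibody would need a dose before that sample, which was not checked. Of 10 splits of the day 0 libraries, the real one included, 3 gave at least the real 62 genes (2 of the 9 others, highest other 465) and 4 at least the real 14 lists (3 of the 9 others, highest other 16). These splits are too few for a share under 0.05.

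Epidermal differentiation genes had higher medians under adalimumab on days 7 (2.40) and 10 (3.06), but 0 of 21 genes passed on either day, and the list had adjusted p = 0.965 and 0.931 with an estimated correlation. Adalimumab day 7 replicate 1, with a score of -0.73, lay among the day 7 controls (-0.76 to -0.65). The library of day 7 with female transcripts, rightly labelled or not, is argued against as the sole source of the day 7 median. That median was 2.39 without it and 2.40 with it. Whether it is a main source stays open, because the other adalimumab libraries of day 7 scored -0.73 and 2.3. Without it the day 7 rise in score rests on replicate 2, and the basal keratinocyte median was 0.31. A difference in library size is argued against by a ratio of 1 between the mean total counts of the arms. More epidermis of the same make-up in the punches could raise these genes, but the differentiation score less the basal keratinocyte score was 1.66 to 2.79 in 5 adalimumab libraries and at most 1.06 in 6 controls (exact two-sided permutation within days, p = 0.005, the smallest that 200 arrangements can give). The 1.66 in this contrast was adalimumab day 7 replicate 1. It came from a low basal score of -2.39, against -1.61 to -0.83 in the day 7 controls, and not from a higher differentiation score. As this contrast was picked after the scores were seen it does not decide, and a faster closing of the epidermis under adalimumab and where the punch was placed both stay open. On day 7 the real count of genes was 0, which all 10 splits reach by construction (highest other 188), so it bears on nothing here. At least the real 7 lists were called in 9 of the 10 splits, the real one included (highest other 15), and on day 10 at least the real 8 in 6 of 10 (highest other 14).

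Counts over splits of the libraries for the other contrasts with 3 libraries in each group came from 10 splits each, the real one included, too few for a share under 0.05. On day 3 the real count was 0, which all 10 splits reach by construction, and the highest other was 574, with adalimumab replicate 1 beside control replicates 1 and 3. For lists the real 16 was reached in 3 of 10, the real one included (highest other 20). On day 0 a split that called 465 genes against the real 62 points to a structure of the samples apart from the arms. In control the real and highest other counts were 7986 and 0 for day 3, 7699 and 1 for day 7, 7951 and 0 for day 10, each reached by 1 split, the real one, and 0 and 0 for day 10 against day 7, where nothing was tested since 10 of 10 reach 0. The animals pair days 0 and 3, and the real split parts all 3 pairs: the 3 other splits that do so gave at most 0 genes, and the 6 that keep a pair together at most 0 in control and 395 in adalimumab. In adalimumab the counts were 4956 and 395 for day 3 and 7500 and 3 for day 7, each again reached by the real split alone. For the day 7 interaction the real count was 0, which 20 of 20 drawn splits reach by construction (highest other 78), so this count is no test of chance.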

How the results depend on the processing

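Settings chosen only after seeing the data were limma voom with sample quality weights, the removal of mitochondrial genes and the joint omission of adalimumab day 0 libraries 2 and 3 or day 3 libraries 1 and 2. For 205 named values, 2654 of 3108 alternatives kept direction and side of the threshold, 325 lost the call, 119 gained one and 10 turned in sign. That tally is favourable by construction, since genes in time contrasts whose call ended without a single library, and Acod1, had been left out of the text. Except where a smaller set of libraries or genes is itself the change, the cause was not tested. Depth did not vary enough to limit 1 group more than another (33080930 to 37494760 counts), but 2 to 3 mice per group recovered only 2% to 30% of simulated changes of log2 1.

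DESeq2 gave 702 genes on day 0, 846 on day 3, 6 on day 7 and 413 on day 10 between the arms, 24 and 5 for day 10 against 7 in control and adalimumab, and 1756, 52 and 392 for the interactions of days 3, 7 and 10. Limma voom gave 7334 (day 0), 2 (day 7) and 5020 (day 10) between the arms, 12446 (control day 7), 108 (control day 10 against 7), 11418, 12216 and 2256 (adalimumab day 7, day 10, and day 10 against 7) and 3849, 1884 and 5134 for the interactions. RLE size factors, the stricter filter and the removal of mitochondrial genes each gave 0 on day 0, and no filter 135 on day 0 and 225 for the day 3 interaction. Fits of the compared groups alone gave 0 on day 0, 1831 on day 10, 1541 and 4612 for adalimumab days 3 and 7, and 0 and 263 for the day 3 and day 10 interactions.

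Both joint omissions, and leaving out either adalimumab day 10 library, leave 1 library in a group, which is assumed to vary like the other groups. Omitting adalimumab day 0 libraries 2 and 3 gave 0 on day 0, 825, 2931 and 737 for adalimumab days 3, 7 and 10, and 0 for the day 3 interaction. Omitting day 3 libraries 1 and 2 gave 1616 for adalimumab day 3 and 0 for that interaction. Lists called fell to 0 on days 0, 3, 7 and 10 with an estimated correlation, and to 2, 0, 0 and 0 with fry. Against day 0, fry called 16, 18 and 16 lists in control and 17, 17 and 13 in adalimumab on days 3, 7 and 10, where camera called 15, 16 and 17, and 19, 19 and 22, and the estimated correlation 0, 0 and 0, and 0, 0 and 2. Fry tests whether a list changed at all, and camera whether it changed more than the other genes. Similar counts from the 2 tests therefore do not back the camera calls. For day 10 against 7 fry called 0 in either arm, and for the interactions 1, 0 and 0.

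With the animal as a block, which pairs days 0 and 3, control day 3 gave 5148, adalimumab day 3 gave 1518 and the day 3 interaction 0. That block was fitted to days 0 and 3 alone. Unpaired fits of the compared groups alone gave 6552, 1541 and 0. The pairing thus cannot be told apart from the smaller set of libraries as the source of these falls. The replicate number does not pair the arms: of 11 same-numbered pairs 4 had a correlation over 0.1 (-0.36 to 0.22), and 9 of 23 libraries correlated best with their own number. That replicate block gave 0 genes on day 0 and moved no other count of genes by more than 1.5 times, and lists numbered 13, 16, 8 and 7 with it.

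Leaving out each library in turn gave 0 to 1503 genes on day 0, 0 to 837 on day 3, 0 to 2 on day 7 and 0 to 0 on day 10, and 10 to 14, 15 to 23, 7 to 13 and 4 to 8 lists. Control gave 5115 to 8834 (day 3), 5160 to 7359 (day 7), 5857 to 6941 (day 10) and 0 to 0 (day 10 against 7), and adalimumab 2919 to 4692, 4730 to 7604, 1004 to 2947 and 0 to 1. The interactions gave 0 to 1778, 0 to 348 and 0 to 560.

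Leaving out a library gave -3.35 to 0.74 for Il1b and -1.56 to 0.89 for Tnf on day 0, -2.40 to 0.05 for Tnf in control day 3, each turned in sign without control day 0 replicate 2, and -1.03 to 4.64 for Il6 on day 3. Signs also turned for Tnf on day 0 (0.58) and Il6 on day 3 (-0.02) with voom, for Il6 on day 3 without adalimumab day 3 replicate 2 (-1.03) or with libraries 1 and 2 omitted (-0.78), and, with adalimumab day 0 libraries 2 and 3 omitted, for Lrrc15 on day 0 (-0.62) and Mki67 (0.83) and Tchh (0.55) in adalimumab day 3.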

Other observations

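The lists with an exact permutation test over days 7 and 10 were compared after the results were seen. The limits of the sex check and of the count of list pairs were set before those tests were run. Both rest on features already seen in the data, namely the female library of day 7 and the list scores.

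Other gene groups also changed with time. In control wounds of day 7, macrophage genes stayed above day 0 in 12 of 16 cases (13 adjusted over the list alone; median 2.22), proliferation genes in 18 of 22 (21 alone; 1.23) and interferon response genes in 19 of 28 (21 alone; 1.89), each with adjusted p = 0.498 with an estimated correlation. In adalimumab wounds of day 7 all 8 melanocyte genes fell against day 0 (median -6.63, adjusted p = 0.391 with an estimated correlation), beside melanocyte scores of 5.67 and 5.86 in 2 of the 3 day 0 libraries. In adalimumab wounds of day 10, wound-edge keratinocyte genes rose in 9 of 19 (11 alone; median 3.58), interferon response genes in 14 of 28 (22 alone; 1.69), neutrophil genes in 10 of 19 (11 alone; 3.37) and B and plasma cell genes in 3 of 9 (3 alone; 2.34). Their adjusted p was 0.382, 0.382, 0.163 and 0.382 with an estimated correlation. Erythrocyte genes, which make haemoglobin and red cell proteins, rose by day 3 in adalimumab wounds in 7 of 8 (median 3.68, adjusted p = 0.39 with an estimated correlation) and in 0 of 8 in control (median 0.49, with camera adjusted p = 0.81). Tested as an interaction, 0 of 8 passed (5 adjusted over the list alone; camera adjusted p = 0.00204, and 0.458 with an estimated correlation).

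Over days 7 and 10 together, exact two-sided permutation tests within days on list scores gave the smallest p for epidermal differentiation (mean difference 2.62, p = 0.01, adjusted p = 0.3 over 30 lists, 5 against 6 libraries). Hair follicle (1.60, p = 0.02), wound-edge keratinocyte (1.1, p = 0.035), TNF signalling (0.13, p = 0.045) basal keratinocyte (1.06, p = 0.07) and fibrillar collagen and matrix scores (-0.22, p = 0.07) followed in the same exact tests, and none passed after adjustment.

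A hypothesis was that the separation of the arms by differentiation less basal score came from picking a pair out of many. Of 435 pairs of lists, 24 (5.52%) had an exact permutation p as small, but 13 of the 24 held the differentiation list itself and 23 of the 24 a keratinocyte or hair follicle list. The share thus counts the pattern under test, and picking was neither excluded nor shown by it.

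Another hypothesis was that sex, female on day 0 and male on day 7, could be the whole cause of the genes that changed in control. In the female mouse of adalimumab day 7 against adalimumab day 0, 93.9% of 7694 such genes had the same sign. This argues against sex as the whole cause. In adalimumab day 3 against adalimumab day 0, with females only, the share was 84.7%, though its arm and day both differ from the control contrast. Each comparison starts from the adalimumab day 0 group with its hair-rich libraries. The female library of day 7 was the only one of days 7 and 10 with female transcripts, and whether its label is right is not known. That leaves the 84.7% of adalimumab day 3 as the value that does not depend on this label. A part played by sex was not tested.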
